A study of Mus musculus with 8 samples.

How the data were processed

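Each library held nuclei whose RNA and accessible DNA carry a shared barcode (10x Multiome). The submitters' processing notes name Cell Ranger ARC 2.0.1 and the genome build mm10; other settings are not given in the sources used here. Per the labels, cells of 3 mice with the same treatment were pooled, and granulocytes were removed by flow sorting before the nuclei were permeabilized. The deposited matrices hold raw counts for each feature and nucleus, UMIs for genes and counts of ATAC signal for peaks, with no normalization. Other deposited files list barcodes, gene identifiers and peak intervals, and each library has its own peak intervals, so that peaks were called per library. The peak lists hold intervals and no score. Count matrices of the BRM014 libraries were used; those of the vehicle libraries were not analysed here. In the marrow BRM014 list 2 peak lines hold no interval, and they and their 254 counts were left out.

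Samples were grouped by tissue and treatment from their titles. Gene positions came from a RefSeq gene table for GRCm38.p6, the assembly that mm10 names, which placed 26296 of the 32285 gene symbols on a chromosome, 20655 of them protein coding. The table gives no strand in the form used here, so the nearest of both gene ends stood in for the gene start that had been planned. A peak within 1 kb of a gene end is called gene end, another peak inside a gene is called gene body, and the rest are intergenic; gene body and intergenic peaks together are distal. No genome sequence was used, so the planned comparison of motifs was not run, and peaks were not split by exon and intron.

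Peaks of opposite treatments were matched by an overlap of at least 1 bp (bedtools 2.31.1). The SD over chromosomes 1 to 19 and X describes how even a share is along the genome and is not a replicate error. For a gene list, peaks with their midpoint within 50 kb of a gene end were counted in each library, 0.5 was added to the sums, and the log2 ratio relative to all peaks was placed among 10000 random lists of equal size, matched in 20 bins of vehicle peak number. Genes are not replicates, so the percentile describes these libraries. A peak near more than 1 gene of a list was counted for each of these genes. The random lists were matched on neither such sharing nor RNA level. The 30 lists hold cell type markers and groups of genes by function; some genes stand in more than 1 list. On simulated data the overlap step called 100.0% of 60000 peaks as made, 2.50% of 200 unchanged lists of 12 genes fell outside the central 95% range, and 100.0% of 200 such lists with 40% of their treated peaks removed were found below it. The simulated peaks stood apart, partners were shifted by less than the gaps, and lost ones were removed outright. The overlap result therefore checks the code only and says nothing of the shares below.

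Nuclei were kept with at least 500 UMIs, 250 genes, 1000 ATAC counts and at most 20% mitochondrial UMIs. This left 7742 of 13472 blood and 1019 of 8385 marrow barcodes. The median over all barcodes was 640.0 UMIs and 301 genes in blood, and 528 UMIs and 149 genes in marrow. Doublets were called with Scrublet in scanpy 1.11.5 and left out. The caller marked 38 of 7780 passing blood nuclei (0.488%) and 1 of 1020 marrow nuclei. These calls are few and the caller was not tested, so neither library can be taken as free of doublets. UMIs were scaled to 1000 per nucleus and log transformed, 2000 variable genes and 30 components were used, and both libraries were clustered together (Leiden, resolution 1, 15 neighbours, seed 0). The added ATAC classes used nuclei with at least 1000 ATAC counts and 60000 regions called in both libraries. The filters on UMIs, genes, mitochondrial UMIs and called doublets were not applied to them.

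A cluster was named from markers fixed beforehand. It needed a mean log2 marker fold of at least 1, a lead of 0.75 over the next class, 3 detected markers and more markers of its own than of other classes among its top 10 genes; a cluster of low depth with none of its markers there stayed unnamed. This scoring rule was set after the data were examined, and the lead and the stricter condition on the top 10 genes were added after a first run had named mixed clusters as stem and progenitor cell-like or erythroid cell-like. Blood and marrow were compared within classes of at least 100 nuclei in both, over genes with at least 20 UMIs, as a ratio of summed UMIs scaled to the total of the class (CPM). The ratio has an exact conditional binomial interval at the 95% level, sums an exact Poisson interval and shares an exact binomial one, all for counting error alone. A count of 0 in a ratio was put at the floor of 3 counts. On simulated data with the depth of monocyte-like nuclei (RNA classes, 3160 genes), the interval held the true ratio for 96.0% of unchanged genes and excluded 1 for 96.0% of changed genes; for B cell-like nuclei (ATAC classes, 6811 genes) these were 97.0% and 84.7%.

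The comparisons, markers, gene lists, filters and the rule for naming genes were fixed before the data were examined. That rule names the 10 protein-coding loci with the largest deficit and excess of peaks in each tissue, the 10 genes in each direction whose interval lies farthest from 1 in a class, and any listed gene; in the text, examples from lists were picked for the size of their difference. Some loci and genes from these sets are not reported here. Other overlaps, windows, widths, locus sizes, filters, resolutions and scalings were tried as alternatives. Tools were Python 3.11.15, numpy 2.4.6, scipy 1.17.1, pandas 2.3.3, scikit-learn 1.9.0, anndata 0.12.19, igraph 0.11.9 and matplotlib 3.10.9.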

Results

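Chromatin accessibility and RNA were measured in the same nuclei of blood and bone marrow from C57BL/6 mice, a common inbred laboratory strain. The mice received BRM014, which blocks SMARCA2 and SMARCA4, the ATPases that drive SWI/SNF chromatin remodelling complexes, or its vehicle of 10% DMSO and 1% methylcellulose. BRM014 was dosed by mouth at 20 mg/kg each day over 14 days, and tissue was collected 18 h later from 3 mice that were pooled into a library. The 4 libraries cover 2 tissues, with 1 library per tissue and treatment, and their RNA and ATAC data make up 8 samples. No group has a replicate, so no difference below has a replicate check and no test between groups was made.

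The blood libraries held 9647 barcodes and 111096 called peaks after vehicle, against 13472 barcodes and 100908 peaks after BRM014. In marrow there were 10022 barcodes and 128072 peaks after vehicle, against 8385 barcodes and 124613 peaks after BRM014. Count matrices were used for the 2 BRM014 libraries, with 9333717 RNA UMIs and 38801168 ATAC counts in blood and 4883042 UMIs and 33079036 ATAC counts in marrow. The vehicle count matrices were not analysed here. Vehicle and BRM014 were therefore compared by the positions of their peaks, and RNA was compared between blood and marrow of treated mice.

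The comparison of vehicle with BRM014 in blood asks which accessible regions differ after inhibition of the SWI/SNF ATPases. In blood, 37638 of the 111096 vehicle peaks, 33.9% ± 2.79 (SD over 20 chromosomes), had no overlapping BRM014 peak. Peaks at gene ends were mostly kept, with 14.3% lacking a partner, while 37.8% of gene body peaks and 38.6% of intergenic peaks lacked a partner. The loci with the largest deficit were Zfp608, a zinc finger gene on chromosome 18 (54888045 to 54992591), with 33 vehicle and 15 BRM014 peaks, Plb1, encoding phospholipase B, with 25 and 9, and Swap70, a gene of B cell activation, with 27 and 12. Next came the death domain adaptor gene Cradd with 31 and 17, the Ano10 locus with 37 and 23, the meiotic gene Mnd1 with 33 and 19, the neuregulin gene Nrg2 with 17 and 4, the Pkib locus with 24 and 11, the tankyrase gene Tnks with 28 and 15, and the diacylglycerol kinase gene Dgkg with 25 and 12.

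Marrow showed the same order of positions. Of the 128072 marrow vehicle peaks, 37208, or 29.1% ± 2.71 (SD over 20 chromosomes), had no BRM014 peak. The shares were 12.3% at gene ends, 32.2% in gene bodies and 32.7% between genes. Fam81a had 25 vehicle and 7 BRM014 peaks, Pced1b had 43 and 26, and Nrp1, which encodes a receptor for semaphorins and VEGF, had 32 and 17. Further loci with fewer peaks after BRM014 were Pgm5 with 30 and 16, Shroom3 with 23 and 10, Lrrc1 with 30 and 17, the netrin gene Ntn4 with 30 and 17, Sel1l3 with 18 and 6, Nrg2 with 28 and 16, and the alpha kinase gene Alpk1 with 35 and 23. Nrg2 was among the 10 largest deficits in both tissues.

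For scale, 17.4% of the blood vehicle peaks had no partner in the marrow vehicle list, and 28.2% of the marrow vehicle peaks had none in the blood vehicle list. Of the marrow BRM014 peaks, 34.96% had no partner in the blood BRM014 list. The lists differ in length, which bears on these shares, so treatment and tissue are not ranked. Over all distal peaks, those more than 1 kb from either gene end, 38.1% in blood (SD 2.86 over chromosomes) and 32.4% in marrow (SD 3.11) lacked a BRM014 partner. Narrow distal peaks lacked one more often, at 49.95% in the narrowest width quartile and 29.9% in the widest in blood, and at 43.7% and 25.2% in marrow.

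**Figure D1:**
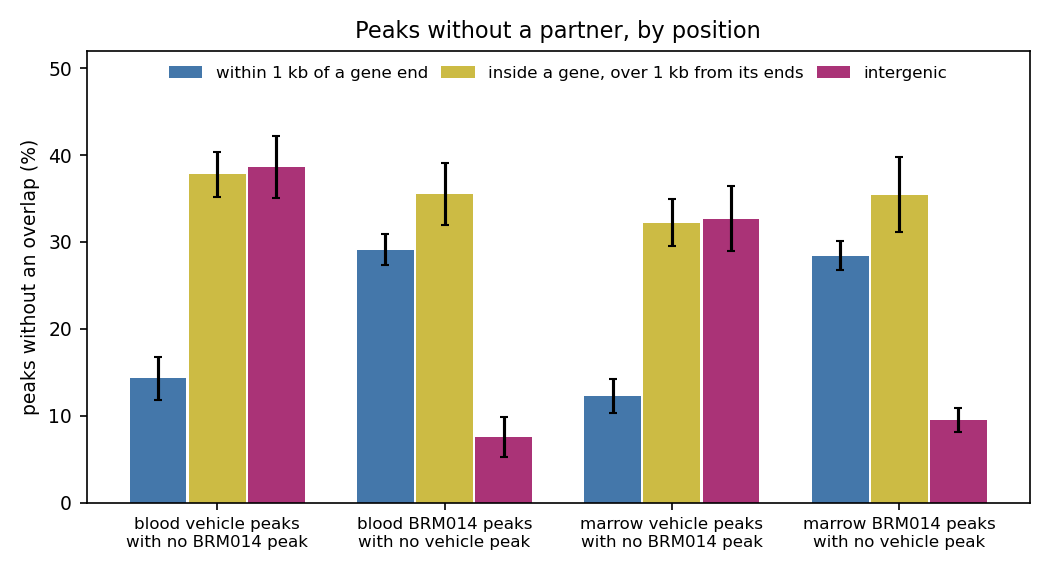
Percent of peaks without an overlapping peak in the opposite treatment of the same tissue, split by position relative to genes; error bars are the SD over 20 chromosomes. Vehicle peaks at gene ends mostly keep a partner (14.3% without one in blood), and few intergenic BRM014 peaks lack one (7.56% in blood).

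Peaks seen after BRM014 and not after vehicle lay in and at genes. In blood, 27326 BRM014 peaks (27.1% ± 2.46, SD over chromosomes) had no vehicle peak, and in marrow 33592 (27.0% ± 2.62). In blood this was the case for 29.1% of BRM014 peaks at gene ends, 35.5% in gene bodies and 7.56% between genes, and in marrow for 28.4%, 35.4% and 9.57%. Among genes of 10 kb or more with a peak at an end, 22.8% had a peak at both ends in blood after vehicle and 59.8% after BRM014, and in marrow 24.96% and 61.3%. Peaks over 1000 bp wide made up 9.50% of the blood and 6.96% of the marrow BRM014 list, and 0.169% and 0.183% of the vehicle lists.

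Pbrm1, a subunit of the PBAF form of SWI/SNF (chromosome 14, 31019138 to 31121592), had 10 peaks after vehicle and 37 after BRM014 in blood, and 13 and 37 in marrow. Blood loci with an excess also included Smg1, a kinase gene of nonsense-mediated decay, with 22 and 46 peaks, the histone acetyltransferase gene Crebbp with 10 and 33, the calpastatin gene Cast with 5 and 27, and Rnf213 with 24 and 46. The cohesin regulator gene Pds5a had 14 and 36, the histone deubiquitinase gene Usp16 had 8 and 28, and the topoisomerase gene Top2b had 10 and 30. Prg4 had 6 and 33 in blood, and this gene overlaps the end of the nuclear pore gene Tpr, which had the largest excess in marrow with 11 and 40. Marrow loci with an excess also included Smchd1 with 20 and 47 peaks, Atf7ip with 28 and 51, the histone methyltransferase gene Ezh2 with 7 and 30, the corepressor gene Ncor1 with 12 and 34, the autophagy kinase gene Ulk2 with 12 and 34, and Ash1l with 14 and 35.

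Peaks called only after BRM014 were denser in genes with more RNA. Genes were put in 10 groups of equal size by the RNA per kb of the treated library, and gene body peaks were counted per 100 kb. From the lowest to the highest group, the density of BRM014-only peaks differed 152-fold in blood and 56.9-fold in marrow. The lowest group held 0.0639 such peaks per 100 kb in blood and 0.185 in marrow, so both folds rest on a low base. Vehicle-only peaks differed 4.08-fold and 3.62-fold, and shared peaks 5.21-fold and 3.87-fold. BRM014-only gene body peaks held 2.73% of the blood and 2.69% of the marrow ATAC counts, with a median of 37 and 27 counts a peak, against 122 and 91 for shared gene body peaks.

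**Figure D2:**
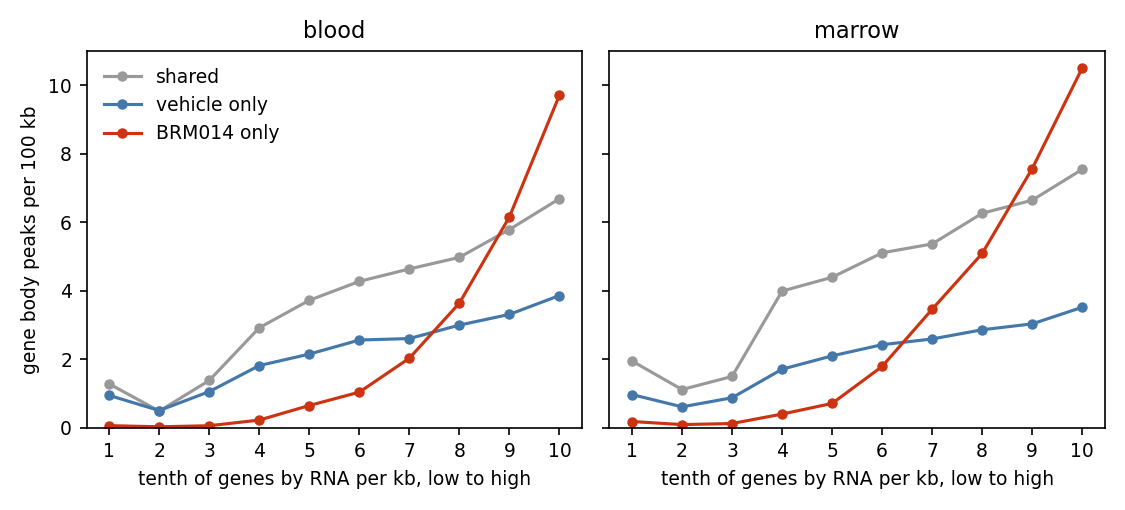
Called gene body peaks per 100 kb (y axis) over 10 equal groups of genes ranked by RNA per kb in the BRM014 library of the same tissue (x axis); lines separate shared, vehicle-only and BRM014-only peaks. BRM014-only peaks reach 9.70 per 100 kb in blood and 10.5 in marrow in the highest group.

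Gene lists fixed beforehand were then compared by the number of peaks within 50 kb of a gene end. Over all peaks the log2 ratio of BRM014 to vehicle was -0.14 in blood and -0.04 in marrow, and list values are given relative to it. In blood, erythroid markers stood 0.61 above all peaks, with more peaks at 9 of 12 loci, among them Alas2, the first enzyme of red cell heme synthesis, with 3 and 14 peaks, Slc4a1, the anion exchanger band 3, with 14 and 24, and the spectrin gene Sptb with 16 and 26. The heme and iron list stood 0.47 above, with more peaks at 9 of 13 loci, and includes Fech with 9 and 19 and the shared member Alas2. Cell cycle genes stood 0.42 above in blood, with more peaks at 12 of 20 loci such as Top2a (28 and 39), Cenpf (14 and 23) and Kif11 (14 and 22). Genes of SWI/SNF subunits stood 0.37 above, with more peaks at 15 and fewer at 9 of 28 loci. Among them, Smarca4 had 17 and 29 peaks and Smarcc1 10 and 23, while Smarca2 had 17 and 16.

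Antigen presentation genes of MHC class II stood 0.34 above in blood, with more peaks at 10 of 11 loci, such as H2-DMa (36 and 44), Cd74 (18 and 22) and the protease gene Ctss (10 and 20), while their activator Ciita had 24 and 18. Loci of neighbouring genes, such as the H2 genes, can overlap, and a shared peak was counted for each gene. Such loci are not separate, and the random lists used below were not matched on this. T cell markers stood 0.29 above, with more peaks at 9 of 15 loci, among them Cd3g (18 and 27) and Trac (16 and 23), while Bcl11b had 36 and 29. Loci of the Cd3 genes can overlap in the same way. At the low end, inflammatory cytokines and receptors stood -0.07 from all peaks, with fewer peaks at 14 of 16 loci, such as Il1b (16 and 11), Tnfaip3 (21 and 15) and Cxcl2 (11 and 7). Myeloid genes linked to the transcription factor PU.1 stood 0.00 from all peaks, with fewer peaks at 18 of 29 loci, among them the Fc receptor gene Fcgr3 (29 and 18), Irf8 (35 and 26) and Ncf4 (17 and 10), while Spi1, which encodes PU.1, had 18 and 23.

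These 8 of 30 lists fell outside the central 95% of 10000 random gene lists matched on size and vehicle peak number. Independent lists would put 1.5 outside by chance, but that number does not apply here. The lists share genes, and the random lists were not matched on RNA level, which BRM014-only gene body peaks follow. Fewer lists lay outside with loci of 100 kb. The random lists matched to the PU.1 list had a median of 0.15, so its 0.00 lay at percentile 1.35, and the inflammatory list lay at percentile 0.410. The inflammatory value turned to 0.15 with loci of 10 kb, 0.00493 with loci of 100 kb and 0.13 with intergenic peaks, and under these settings both lists lay inside the random range. With intergenic peaks alone, a choice added after the data were examined, the erythroid list stood at -0.25 and the cell cycle list at -0.15 in blood, and 3 of 30 lists lay outside the range. Of the 8 lists above, MHC class II at 0.41 and SWI/SNF subunits at 0.34 stayed outside, and NK cell markers at 0.50 lay outside in addition.

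In marrow, 5 of 30 lists fell outside. More lists did so with loci of 10 kb, and fewer with loci of 100 kb. Cell cycle genes stood 0.47 above all peaks, with more peaks at 15 of 20 loci such as Ezh2 (7 and 30), Top2a (27 and 39) and Cenpe (11 and 22). Granulocyte-monocyte progenitor markers stood 0.41 above, with more peaks at 6 of 7 loci, among them the granule protease genes Elane (22 and 30) and Ctsg (4 and 11) and the myeloperoxidase gene Mpo (20 and 26). Erythroid markers stood 0.40 above, with Alas2 at 6 and 19, Sptb at 18 and 30 and Slc4a1 at 17 and 26. SWI/SNF subunit genes stood 0.31 above, with more peaks at 18 of 28 loci, among them Smarca4 (24 and 37), Arid2 (18 and 34) and Smarcc1 (13 and 23). Stromal and endothelial markers stood -0.29 from all peaks, with fewer peaks at 4 of 8 loci, among them the chemokine gene Cxcl12 (10 and 5) and the endothelial cadherin gene Cdh5 (22 and 14). With intergenic peaks alone none of these 5 lists stayed outside the random range, with erythroid markers at 0.04, cell cycle genes at 0.08 and SWI/SNF subunits at 0.11.

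**Figure D3:**
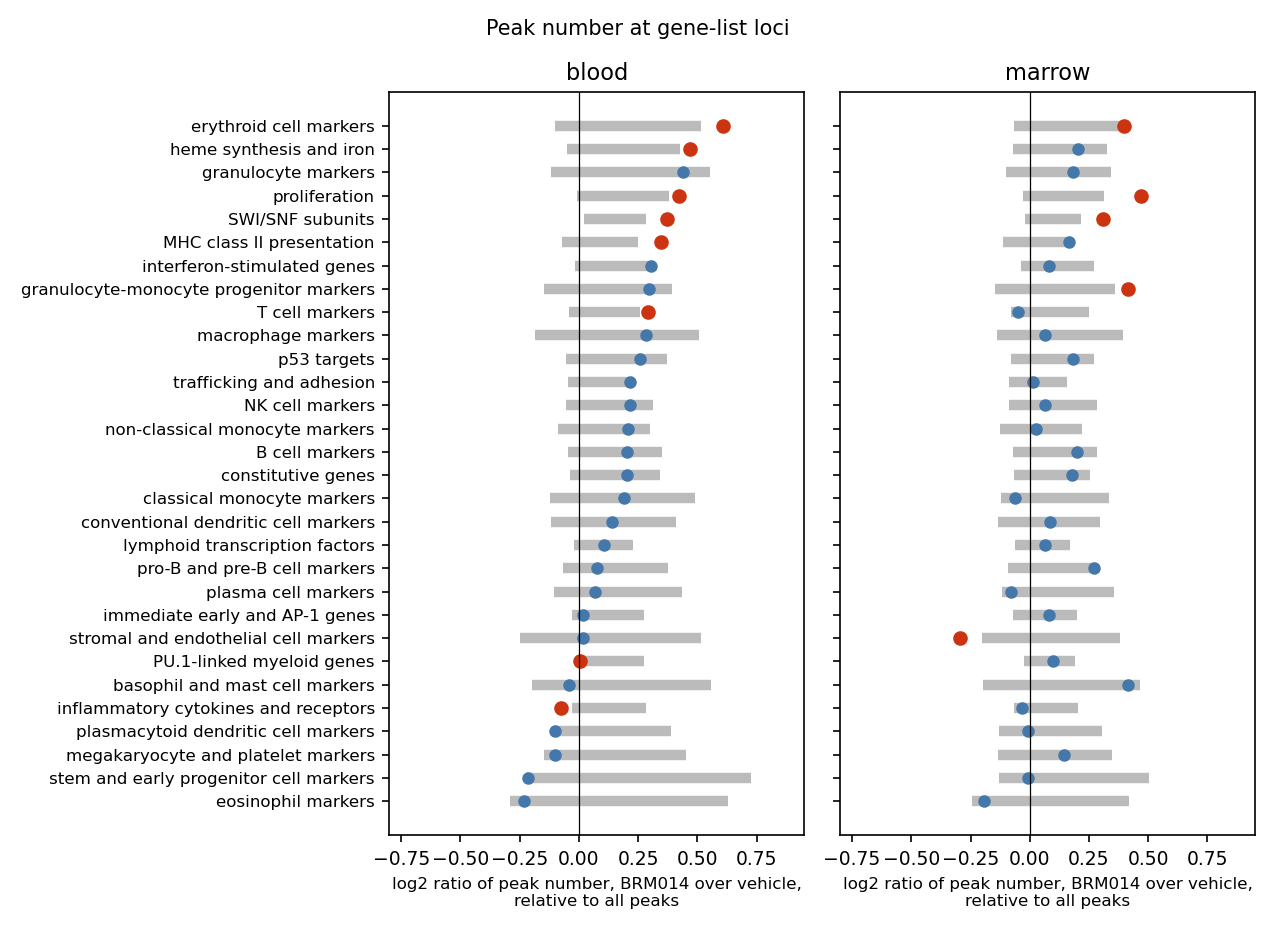
Log2 ratio of peak number, BRM014 over vehicle, relative to all peaks (x axis) for 30 gene lists in blood and marrow. Grey bars span the central 95% of matched random lists and red points lie outside them, 8 in blood and 5 in marrow.

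The treated libraries were next described by cell class. Treated blood consisted mainly of lymphocytes. Of 7742 nuclei that passed the filters, 51.9% were T cell-like (95% interval 50.75 to 52.99), 32.5% B cell-like (31.4 to 33.5), 12.6% NK cell-like (11.9 to 13.4) and 2.42% classical monocyte-like (2.08 to 2.78). Of 1019 marrow nuclei, 35.2% were classical monocyte-like (32.3 to 38.3), 5.69% NK cell-like (4.35 to 7.30), 1.08% B cell-like (0.540 to 1.92) and 0.589% T cell-like (0.216 to 1.28). A further 57.4% of marrow and 0.620% of blood nuclei lay in a cluster with Meis1, Angpt1 and Flt3 among its top 10 genes. It scored highest for stem and early progenitor cells (2.29) and next for plasmacytoid dendritic cells (1.34), and it stayed unnamed. By ATAC, 230 of its nuclei were plasmacytoid dendritic cell-like, 36 pro-B and pre-B cell-like and 303 unnamed. The intervals are exact binomial ones and cover counting error only, while the clustering moved the shares far more: at resolution 2 blood held 3.25% T cell-like and 15.2% B cell-like nuclei with 66.0% unnamed, and blood clustered alone had no cluster named T cell-like and 55.6% unnamed. The filters kept 57.7% of blood and 12.2% of marrow barcodes, and per the labels granulocytes were sorted out and blood red cells lysed, all of which can set these shares.

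Classes built from ATAC counts, an addition made after the data were examined, took in more marrow nuclei. Their nuclei were filtered on ATAC counts alone, with called doublets kept. Of 7490 marrow nuclei, 13.2% were granulocyte-like (12.4 to 14.0), 12.2% classical monocyte-like (11.50 to 12.99), 9.31% pro-B and pre-B cell-like (8.66 to 9.99), 7.56% B cell-like (6.97 to 8.18), 7.53% plasmacytoid dendritic cell-like (6.94 to 8.15) and 1.67% erythroid cell-like (1.39 to 1.99). Of 11475 blood nuclei, 55.0% were T cell-like, 28.2% B cell-like, 10.7% NK cell-like and 1.25% classical monocyte-like, and 0.122% were granulocyte-like. Clusters that the naming rule left without a name held 46.3% of marrow and 4.72% of blood nuclei.

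**Figure D4:**
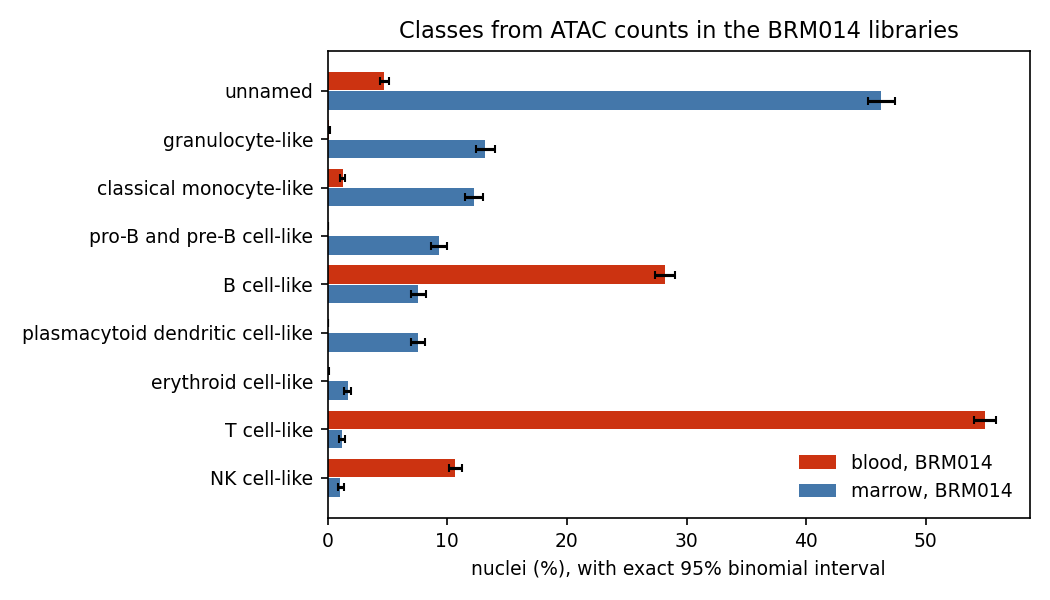
Percent of nuclei (x axis) per class from ATAC counts in the BRM014 libraries of blood (11475 nuclei) and marrow (7490 nuclei), with exact 95% binomial intervals. T cell-like nuclei make up 55.0% in blood and 1.16% in marrow.

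The ATAC data of the blood nuclei was read at the marker genes of classes named from RNA. Of 48 marker loci of the 4 blood classes, 45 had their highest accessibility, in CPM (ATAC counts scaled to the total of the class) within 10 kb of a gene end, in their own class. Pax5, a transcription factor gene of B cells, reached 210.1 (95% interval 200.4 to 220.1) in B cell-like nuclei and 20.3 (17.9 to 22.9) in T cell-like nuclei. The T cell gene Bcl11b had 137 in T cell-like and 39.4 in NK cell-like nuclei. Ncr1, an NK cell receptor gene, had 113 in NK cell-like nuclei and 7.69 in T cell-like nuclei. The monocyte genes Csf1r and Lyz2 had 140.1 and 2085 in classical monocyte-like nuclei, against 14.3 and 122 in B cell-like nuclei. Loci of T cell markers summed to 2155 in T cell-like and 1469 in NK cell-like nuclei. Intervals of counts here and below are exact and cover counting error only.

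Treated blood and marrow were also compared within a class, which describes tissue and not treatment. Classical monocyte-like nuclei, 187 in blood and 359 in marrow, were the RNA class with at least 100 nuclei in both. At clustering resolution 2 the class had 2 clusters that mostly split by tissue, of 114 blood and 3 marrow nuclei and of 52 blood and 312 marrow nuclei, beside a granulocyte-like cluster of 21 blood and 47 marrow nuclei, and 39 nuclei of the RNA class were granulocyte-like by ATAC. Over 3154 genes the median log2 ratio of blood to marrow CPM was 0.78, and 4 genes with high counts in nearly every nucleus held 19.9% of UMIs in blood and 40.1% in marrow. Values below are relative to that median. Relative to it, the phosphodiesterase gene Pde4b was 2.60 higher in blood (270 UMIs in blood, 36 in marrow) and the adhesion receptor gene Cd44 0.75 higher (554 and 266). The receptor gene Csf1r was 0.79 higher (47 and 22), whereas the monocyte genes Lyz2 and F13a1 stood at -0.72 (139 and 185) and -1.22 (146 and 275). Dusp16 (47 and 2), Cyth3 (31 and 1) and Tgm2 (20 and 0) were also among the largest excesses in blood. With its marrow count put at the floor of 3, Tgm2 was 9.29-fold higher in CPM before centring. The lower end of its counting interval was a log2 ratio of 2.78.

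T cell genes and some broadly expressed genes were also higher on the blood side in these nuclei: Lef1 had 61 UMIs in blood and 2 in marrow, Skap1 53 and 2, Themis 27 and 0, Camk4 25 and 0, the regulator of NF-kB signalling Tnfaip3 88 and 13, the transcription factor gene Runx3 42 and 4, and Taf4b 22 and 0. Lef1 stood at 248 CPM in these blood nuclei, 132 in blood B cell-like, 336 in NK cell-like and 1609 in T cell-like nuclei, while Tnfaip3 stood at 358, 186, 614 and 675 and Runx3 at 171, 25.98, 245 and 124. Doublets or free RNA from other blood cells were not excluded for any of these genes. Granulocyte genes led the marrow side, in a class that takes in granulocyte-like nuclei: S100a8 stood at -4.61 (12 and 237 UMIs), S100a9 at -3.25 (61 and 471), the antimicrobial peptide gene Camp at -3.86 (4 and 47) and Ngp at -2.04 (59 and 196). Also among the marrow excesses, Anp32a had 2 and 26 UMIs, Wfdc21 1 and 19, Adpgk 14 and 60 and Ptms 6 and 34. Cdk8 and Lars2 were abundant in both tissues, with 1386 and 3602 and with 4154 and 10234 UMIs. In the class they stood at 5644 and 10522 CPM and at 16914.5 and 29895 CPM. Over all blood and marrow nuclei they differed in the same direction, at 5640 and 9295 and at 14725 and 26588 CPM. Their excess was thus not particular to the class.

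B cell-like nuclei of the ATAC classes, which were added after the data were examined, 3232 in blood and 566 in marrow, gave a median of 0.94 over 6785 genes, with the 4 high-count genes at 28.0% of UMIs in blood and 52.2% in marrow. These nuclei were filtered on ATAC counts alone. At least 500 UMIs were held by 252 of the 566 marrow nuclei and 2644 of the 3232 blood nuclei. Clustering of all barcodes by RNA named 60 of 8385 marrow barcodes B cell-like and 2490 pro-B and pre-B cell-like, so the marrow side rests on the ATAC naming and was not shown to be free of pro-B and pre-B cells. Relative to the median, Foxo1, a transcription factor gene of naive lymphocytes, was 1.49 higher in blood (3219 and 74 UMIs), the heparan sulfate enzyme gene Hs3st1 3.88 higher (455 and 2), and Fam117b 2.60 higher (752 and 8). Of 15 measured genes of trafficking and adhesion, 5 stood above the median of all genes and 10 below it. Above it were the egress and homing genes Klf2 at 1.12 (236 and 7), S1pr1 at 1.11 (201 and 6), Cxcr4 at 0.86 (169 and 6) and Ccr7 at 0.71 (305 and 12) and the integrin gene Itga4 at 0.56 (1327 and 58), though the counting intervals of S1pr1, Cxcr4 and Ccr7 include the median. Below it were Ccr2 at -2.63 (15 and 6), the leukocyte integrin gene Itgb2 at -1.10 (94 and 13) and Cd44 at -0.58 (1023 and 99), and the list median was -0.56, at percentile 0.610 of 10000 matched random lists. Cell cycle genes had a median of -1.43 over 10 measured genes, lower than in any of the random lists, with Mki67 at -2.90 (29 and 14) and Top2a at -2.74 (37 and 16). The 12 B cell markers had a median of -0.12, at percentile 5.35, with Bank1 at 0.60 and Cd22 at -0.68.

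Further genes with a large excess in blood B cell-like nuclei were Fam107b (6993 and 136 UMIs), Gdi2 (955 and 14), Pdcd4 (2256 and 41), Rnf145 (777 and 11) and Cyth1 (4657 and 98). The ubiquitin ligase gene Cblb (2322 and 35) and Pde3b (2296 and 37) also had an excess, but stood at 989 and 978 CPM in these nuclei against 1618 and 1091 over all blood nuclei. Fam107b and Pdcd4 stood close to their values over all blood nuclei, at 2979 against 2629 and 961 against 842 CPM. Gdi2, Rnf145 and Cyth1 stood higher, at 407, 331 and 1984 against 193, 204 and 1039 CPM. RNA from other blood cells was not excluded for any of these genes. The marrow side was again led by granulocyte genes, with Lcn2 at -5.76 (10 and 35), S100a9 at -5.02 (70 and 147), Ngp at -5.20 (24 and 57) and Ltf at -4.92 (19 and 37). It also held the histone gene Hist1h1b at -3.61 (19 and 15), Anxa1 at -3.54 (20 and 15) and Angpt1 at -3.82 (11 and 10). Anxa1 and Angpt1 stood lower in these marrow nuclei than over all marrow nuclei, at 51.7 against 71.9 and 34.4 against 120 CPM. Hist1h1b stood higher, at 51.7 against 38.3 CPM. RNA from other marrow cells was not excluded for any gene of the marrow side. Classical monocyte-like nuclei of the ATAC classes, 144 in blood and 916 in marrow, had a median of 0.90. There the granulocyte gene S100a9 had 1 UMI in blood and 461 in marrow, against 61 and 471 in the RNA class, and Ngp 1 and 170, against 59 and 196.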

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

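The tests of depth, of a library or calling batch and of weak peaks were chosen only after the result was seen, as was the gradient over groups of genes by RNA, while the slope test and the test of myeloid nuclei were written beforehand.

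T cell markers had more peaks after BRM014 in blood and not in marrow, relative to all peaks: 0.29 and -0.05 on the log2 scale, a difference of 0.34 between the tissues that was not tested. Stromal and endothelial markers stood at 0.02 in blood and -0.29 in marrow, a difference of 0.31, also not tested. Both stood out because the value had opposite signs in the tissues. These signs are relative to all peaks, and matched random lists need not centre there, as seen above in blood. The signs can therefore depend on this baseline.

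Peaks called only after BRM014 lie in and at transcribed genes, as at Pbrm1. More barcodes are argued against as the cause in marrow, where the BRM014 library had fewer than its vehicle library. More depth stays open in both tissues, and more nuclei in blood. The share of intergenic BRM014 peaks without a vehicle peak was at most 0.270 of the gene body share. That ratio restates the pattern and cannot decide, and the ATAC depth of the vehicle libraries was not analysed. Signal that follows transcription stays open: between blood B cell-like and T cell-like nuclei, ATAC counts of BRM014-only gene body peaks rose with RNA over 1567 genes with a slope of 0.467 (SD 0.0168), but not above the slope of shared peaks, 0.650 (SD 0.0273; difference -0.18, 95% interval -0.24 to -0.12), which met the bound written beforehand against this explanation. After that result was seen, the bound was judged wrong, on the view that shared peaks may include regulatory elements specific to a class, whose slope the explanation does not limit. That view was not tested. BRM014-only peak density differed 152-fold from the lowest to the highest RNA group in blood against 5.21-fold for shared peaks, but this gradient restates the pattern and decides nothing. A library or calling batch cannot be told apart from the treatment, since peaks over 1000 bp made up at least 6.96% of both BRM014 lists and at most 0.183% of both vehicle lists, and an effect of BRM014 on transcribed chromatin stays open and untested.

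Vehicle peaks without a BRM014 peak were mostly distal in both tissues. Weak peaks near the calling threshold stay open as a cause. The widest quartile of distal peaks lacked a partner at 0.577 or more of the share in the narrowest, with width standing in for strength. Width was not shown to follow strength, and width quartiles 3 and 4 lacked a partner alike (29.7% and 29.9% in blood, 24.9% and 25.2% in marrow). The test therefore cannot tell strong peaks from weak ones. Fewer myeloid nuclei in treated blood stay open: intergenic peaks without a treated blood peak, but with a treated marrow peak, held 1.52 times (1.48 to 1.56 over peaks) the monocyte-like share of treated marrow counts that peaks with both partners held, near the bound of 1.5 set beforehand. This ratio decides nothing, because peaks chosen for absence from treated blood, which is mostly lymphoid, lean to other classes by construction (1.30 for granulocyte-like and 0.387 for B cell-like nuclei), as marrow peaks without a treated marrow peak lean to T cell-like nuclei of treated blood (1.91). A loss within cells after inhibition of the ATPases stays open and untested, since vehicle counts were not analysed here.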

How the results depend on the processing

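Peaks up to 1000 bp, intergenic peaks alone, ATAC classes and 4 high-count genes left out were tests chosen only after the result was seen; the other settings were set beforehand. No paired analysis was possible because all replicate numbers are 1, with 1 library per group. The motif comparison and its alternatives were not run, and T cell-like nuclei have no value where each library was clustered alone. Of the values that answer a comparison, 48 stayed within the limit used for them and 48 moved beyond it. For the median ratios this limit was a spread over genes, and for accessibility at marker loci a fixed factor. No limit was a replicate error. Of gene list values, 191 stayed, 103 moved and 6 changed sign, and of named gene ratios 195 stayed, 50 moved and none changed sign. Where no reason is given, the cause was not tested.

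The share of vehicle peaks with no partner was 17.4% in blood against the vehicle list of the other tissue, and 40.7% in blood and 40.2% in marrow when both lists were limited to peaks wider than the median, which also takes away narrower partners. Blood distal peaks over 10 kb from a gene end gave 41.0%. With intergenic peaks, 3 lists in blood lay outside the random range, and blood values were -0.25 for erythroid markers, -0.15 for proliferation and 0.13 for inflammatory genes, which stood at 0.15 with loci of 10 kb and 0.00493 with loci of 100 kb. PU.1-linked genes stood at -0.00579 with distal peaks. Loci of 10 kb put 10 marrow lists outside, and loci of 100 kb put 4 in blood and 3 in marrow.

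With all barcodes, blood held 41.8% T, 27.6% B, 10.3% NK and 1.78% monocyte-like nuclei, and marrow 0.716% B, 2.84% NK and 11.4% monocyte-like. With at least 1000 UMIs, blood held 38.5% T, 26.2% B, 9.72% NK and 0.583% monocyte-like, and marrow 0 of 304 B (up to 1.21%), 9.87% NK and 23.7% monocyte-like. In that setting 23.9% of blood was unnamed. This part included a cluster of 118 blood nuclei that scored highest for classical monocytes and a cluster of 127 that scored highest for B cells. ATAC classes gave 55.0%, 28.2%, 10.7% and 1.25% in blood, and 7.56% B, 1.07% NK and 12.2% monocyte-like in marrow. Resolution 2 gave 3.25% T and 15.2% B in blood and 0.491% B and 30.9% monocyte-like in marrow, with 66.0% of blood unnamed. Keeping called doublets gave 37.8% T in blood, with 14.3% unnamed. The unnamed part included a cluster of 1089 blood nuclei that scored highest for T cells, so the naming moved. Libraries clustered alone gave 29.9% B in blood, and 10.3% NK and 29.3% monocyte-like in marrow.

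The median log2 ratio of blood to marrow (monocyte-like by RNA, B cell-like and monocyte-like by ATAC) was 0 with median ratio scaling, by construction. It was 0.37, 0.35 and 0.43 without 4 high-count genes, and 0.70, 0.89 and 0.84 with nuclei thinned to 500 UMIs. Thinning left out nuclei under 500 UMIs and kept 2644 of 3232 blood and 252 of 566 marrow B cell-like nuclei. Of ATAC monocyte-like nuclei it kept 139 of 144 in blood and 748 of 916 in marrow. With at least 100 UMIs the ATAC classes gave 1.11 and 0.97, and without mitochondrial UMIs ATAC monocyte-like nuclei gave 0.87.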

Other observations

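The values by class in the next paragraph were chosen only after the result was seen, as were the genes, the dendritic class and the overlap of intervals used for the gene shares of granulocyte RNA and the comparison with granulocyte-like nuclei, while the bounds for free granulocyte RNA were written beforehand.

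RNA of the ATPase genes that BRM014 blocks differed between treated lymphoid classes (ATAC classes), with Smarca4 above Smarca2 in pro-B and pre-B cell-like nuclei and below it in T cell-like nuclei. Smarca4 had 476 CPM (UMIs scaled to the total of the class; 95% interval 408 to 552) in marrow pro-B and pre-B cell-like nuclei, 114 (78.2 to 160) in marrow B cell-like nuclei, 96.0 (86.8 to 106) in blood T cell-like nuclei and 46.8 (30.3 to 69.1) in marrow granulocyte-like nuclei. Smarca2 had 29.9 (14.9 to 53.6) in pro-B and pre-B cell-like nuclei and 275 (259 to 292) in blood T cell-like nuclei. Arid1b, a subunit of the BAF form, had 539 (467 to 620) and 438 (418 to 458) in those classes. Cell cycle genes summed to 2702 (2280 to 3179) in erythroid cell-like, 1007 (907 to 1115) in pro-B and pre-B cell-like and 331 (268 to 404) in B cell-like nuclei of marrow. CPM of marrow classes run low against blood, by a median log2 ratio of 0.94 in B cell-like nuclei, and are not centred here. No vehicle value was analysed beside these, so they say nothing of treatment.

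Granulocytes were sorted out per the labels, but the 10 granulocyte markers summed to 10539 CPM in granulocyte-like nuclei, 1202 in B cell-like, 1236 in pro-B and pre-B cell-like, 1199 in NK cell-like, 936 in plasmacytoid dendritic cell-like and 882 in T cell-like nuclei of marrow, and to 1699 in monocyte-like and 2255 in erythroid cell-like nuclei. Over the lymphoid and dendritic classes the highest sum was 1.40 times the lowest, within the factor of 3 set as the limit. The gene shares were to keep 1 ratio, with no tolerance set beforehand, and their intervals overlapped between classes (Ltf over S100a9 0.143 to 0.409), which is a weak condition with 14 S100a9 UMIs in T cell-like and 22 in NK cell-like nuclei. In a comparison added later the shares differed from granulocyte-like nuclei: Ltf over S100a9 was 0.284 (95% interval 0.234 to 0.343) in lymphoid and dendritic nuclei together and 0.551 (0.511 to 0.594) in granulocyte-like nuclei, Camp 0.0966 (0.0703 to 0.130) and 0.176 (0.157 to 0.198), Ngp 0.398 (0.336 to 0.471) and 0.510 (0.473 to 0.551), and S100a8 0.682 (0.592 to 0.785) and 0.540 (0.501 to 0.582). The profile of RNA outside nuclei was not measured, so free RNA from broken granulocytes stays open, and no biological explanation was tested.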
